A study of Caenorhabditis elegans with 4 samples.

How the data were processed

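Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the binding of LSY-2, a zinc-finger transcription factor, in Caenorhabditis elegans larvae of the first stage (L1) that had been fed and grown at 20 °C. Per the labels' protocols, the worms carried a transgene that expresses LSY-2 fused to green fluorescent protein, chromatin was crosslinked with formaldehyde and sheared by sonication, and antibodies against the fluorescent protein collected the bound fragments. A part of each chromatin sample was kept as input. The study holds 2 ChIP samples and 2 input samples. The labels do not say whether the replicates were separate worm cultures.

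The analysis began from 3 peak lists, 1 for each ChIP replicate and 1 combined list. Per the file headers, positions are in the WormBase WS220 build, and the source field of every entry names SPP, a ChIP-seq peak caller, together with the irreproducible discovery rate (IDR), a procedure that compares peak ranks between replicates. The aligner, the tool versions, the thresholds and the way the input was used are not given in the sources used here. The number attached to each peak is a score that the authors deposited without naming its scale. It is the authors' own value and was used only to describe the lists and to compare matched peaks between replicates. In the combined list 4462 of 6064 peaks (73.6%) tied at the highest score, so peaks were ranked by the number in the peak name, where 1 is the best. The correlation of that number with the score over the peaks of a list was -0.763 in the combined list, -0.997 in replicate 1 and -0.998 in replicate 2 (Spearman's rho). How the combined list was made from the replicates is not recorded beyond the name of the method, and its peaks have no replicate error of their own. The lists give no read counts, so the sequencing depth of each sample is unknown. Intervals given for shares of peaks are 95% Wilson intervals over peaks, cover counting error only, and are too narrow to the extent that neighbouring peaks are not independent.

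The main comparisons, the naming of the 25 best-ranked peaks and the search for discordant peaks among the best 500 were planned before the data were examined. The plan ranked peaks by the authors' score. Ranking by the number in the peak name replaced it because of the ties, and it decided which 25 and 500 peaks were used. The plan asked for the ranks that differ most and did not name their ratio as the measure. Named regions are the 25 best-ranked combined peaks, described in full for the first few, and the 5 of the best 500 with the largest ratio of ranks between replicates. The rule had been written for the genes of those peaks and was applied to the peaks themselves. Windows, bins and gaps named for their counts were picked after these were seen. Gene positions, gene lists, gene classes, the lsy-2 and unc-119 loci and the sequence under peaks had also been planned and were not analysed here, because the gene table at hand is on another build (WBcel235), has no strand, and comes with no sequence; coordinates of different builds were not mixed. For the same reason the planned chromosome test on genes with a peak was replaced by a test on 1 Mb bins. The comparisons of central and outer segments, of the share of each chromosome's peaks among the 1516 strongest, of neighbouring peaks and of gaps were chosen after the lists had been seen.

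Peaks overlapped when they shared at least 1 bp. Chance overlap was measured by shifting the second list around each chromosome by a random distance of 5 to 95% of its length, 1000 times, and p-values are one-sided. Chromosome spans were taken as the largest peak end in any of the 3 lists. Peaks per Mb were counted in whole 1 Mb bins by peak centre, and a chromosome was compared with the other 5 by a two-sided permutation test of bins (100000 permutations) with Benjamini-Hochberg adjustment over 6 chromosomes. Neighbouring bins are not independent, so these p-values are too small; a second test moved the chromosome labels along the ordered bins, which gives 97 placements and a smallest unadjusted p of 0.01; a chromosome that reaches it alone has an adjusted p of 0.062. Each chromosome was also divided into 3 segments of equal length, and the central segment was compared with the outer ones by shifting the peaks around each chromosome 10000 times (two-sided). The share of each chromosome's peaks that are among the 1516 strongest was compared with that of the other 5 by the same 2 permutation tests, both two-sided. Close neighbours were peaks with centres within 1 kb, and their chance number came from redrawing every position within its own 100 kb window 1000 times (one-sided); the count was repeated with overlapping intervals merged into regions and redrawn without overlap. For values per replicate, the 6064 best-ranked peaks of each list were used, which is the size of the combined list; 24 of them in replicate 1 and 22 in replicate 2 were mitochondrial and were left out of nuclear comparisons. No test across the 2 replicates was made, and replicate values are given side by side or as mean ± SD.

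Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used. The procedures were tested on simulated lists of 6064 peaks, 20 lists per setting, in which sites did not cluster as real ones do. With 60% of sites shared, the mean overlap recovered was 61.5%. All 40 chromosomes simulated with a changed density were called (log2 ratios of 0.82 on III and -0.88 on V), and no evenly spread list gave a call in the tests of chromosomes, strongest peaks, segments or merged neighbours, while 1 of 20 pairs of independent lists passed the overlap test at 0.05. The simulated changes were larger than those observed in the combined list (0.64 on III and -0.69 on V). Chromosomes and strongest peaks were judged by the permutation of bins alone, and the test with moved labels was not assessed. Alternatives covered the overlap rule, stricter peak sets, each replicate on its own, repeated intervals, the bin size and the permutation scheme.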

Results

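The binding regions of LSY-2 were mapped in fed L1 larvae in 2 ChIP replicates, beside 2 input samples that are not analysed here. LSY-2 is a zinc-finger transcription factor known for its part in the left-right asymmetry of the ASE taste neurons. Each replicate list held exactly 30000 entries, and the combined list held 6064. The same round number in both replicates looks like a set list length, so it is not read as a count of binding regions. Scores ran from 3.99 down to 0.16 in replicate 1 and from 3.78 down to 0.15 in replicate 2, so weak entries were kept. The combined peaks covered 1.84 Mb, or 1.84% of the nuclear span, against 10.3% for replicate 1 and 9.21% for replicate 2. Most entries of a list had the same width: 63.4% of combined peaks were exactly 350 bp wide, 94.8% of replicate 1 entries were 370 bp and 95.9% of replicate 2 entries were 320 bp. A few entries repeated the interval of another entry, which left 6048 distinct combined intervals. Because the common widths differ between the replicates, most intervals could not have the same start and end in both, and none did. The combined list placed 1124 peaks on chromosome I, 986 on II, 1200 on III, 950 on IV, 860 on V and 944 on X, and none on the mitochondrial genome. The lists give no read counts, so the depth of each sample is unknown, and no background level from the inputs is set beside the values.

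The strongest binding regions lay on all 6 nuclear chromosomes. The best-ranked combined peak was on chromosome V at 11764237 to 11764855 (WS220) and ranked 1 in both replicates. The next were on chromosome III at 12904855 to 12905344 (ranks 3 and 2 in replicates 1 and 2), on chromosome IV at 654662 to 655197 (ranks 2 and 3), on chromosome I at 9619758 to 9620234 (rank 4 in both) and on chromosome II at 8184906 to 8185372 (ranks 8 and 5). Chromosome IV also held the peaks ranked 6 and 7, at 4749811 to 4750300 and at 1094128 to 1094594. The peak ranked 8 lay on chromosome III at 3867302 to 3867821, and those ranked 9 and 10 on chromosome II at 3076896 to 3077363 and at 10868679 to 10869161. The best-ranked peak on X was at 15840984 to 15841427 and ranked 11. Of the 25 best-ranked peaks, 8 were on III, 5 on I, 5 on IV, 4 on II, 2 on X and 1 on V. They were 435 to 619 bp wide with a median of 468 bp, above the 350 bp that most combined peaks share. The best 500 combined peaks were not wider than that, with a median of 318 bp. All 25 were within the best 40 of both replicates.

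The first question was how far the replicates found the same regions. In replicate 1, 18147 of 29974 nuclear peaks (60.5%, 95% interval 59.99 to 61.1) overlapped a replicate 2 peak, against 19.4% on average for shifted lists. In the other direction 58.2% (57.6 to 58.8) overlapped, against 18.9%. Among the 6064 best-ranked entries of each list the overlap was 75.8% (74.7 to 76.8) of replicate 1 and 74.9% (73.7 to 75.9) of replicate 2, against 3.91% and 3.88% by chance. In each of these comparisons no shifted list reached the observed value (permutation p = 0.001, the smallest that 1000 shifts can give). Agreement fell with rank, so the overlap over all 30000 entries depends on how many weak entries a list keeps. Of the 2986 nuclear peaks among ranks 1 to 3000 of replicate 1, 99.3% overlapped a replicate 2 peak, and of ranks 27001 to 30000, 36% did, which was still above the highest of 100 shifted lists (20.8%). For replicate 2 the values were 98.9% and 33.3%, with a highest shifted value of 20.3% for the last group.

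**Figure D1:**
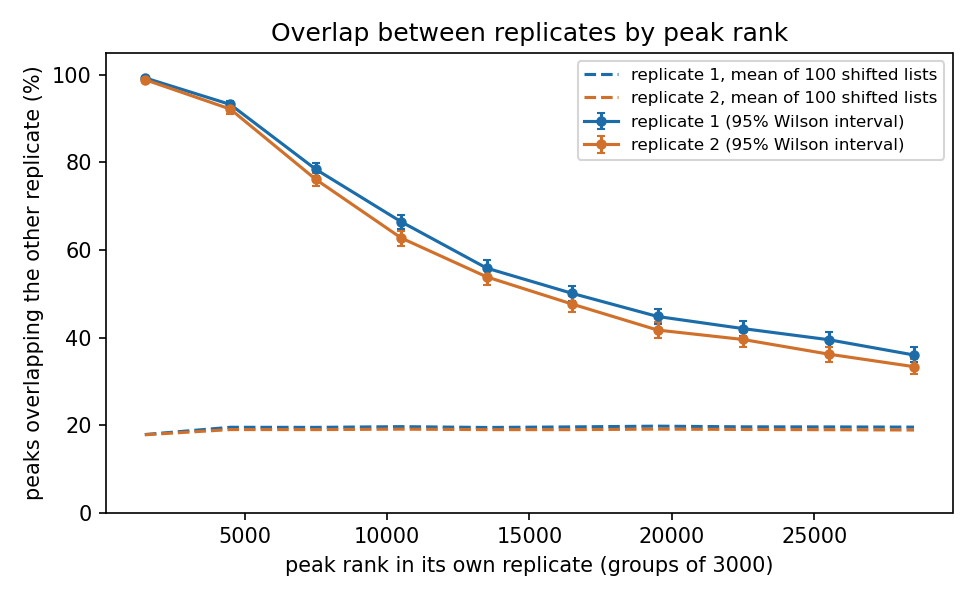
The percentage of nuclear peaks that overlap the other replicate (vertical axis) is plotted against peak rank in groups of 3000 (horizontal axis); points show each replicate with 95% Wilson intervals, and dashed lines the mean of 100 shifted lists. Overlap falls from 99.3% to 36% in replicate 1 and from 98.9% to 33.3% in replicate 2, and stays above the dashed lines throughout.

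The strength of shared regions was related between replicates. Over 16217 nuclear peaks matched one to one, the authors' scores had a Spearman's rho of 0.65 between replicates, and the ranks from the peak names a rho of 0.69. These are correlations across peaks, which are not independent replicates. Among the matched peaks that overlapped the combined list, rho was 0.78 for ranks and 0.41 for scores, many of which tie at the maximum. The source field of the combined list names a method that compares ranks between replicates, so close ranks within that list are in part a matter of selection. The best 500 combined peaks were all within the best 1000 of both replicates, and their ranks differed between replicates by a median of 1.22-fold. Discordance was measured by the ratio of the 2 ranks, which gives small differences among the best ranks much weight. The 5 peaks with the largest ratio are given with their ranks in replicates 1 and 2. The first were on X at 15840984 to 15841427 (19 and 7) and on I at 7090207 to 7090616 (240 and 547). The others were on I at 6554539 to 6554811 (481 and 225), on II at 12102355 to 12102675 (280 and 596) and on X at 16929426 to 16929924 (343 and 729). The greatest of these ratios was 2.71-fold.

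Nearly all combined peaks overlapped entries of both replicates. The source field names a method that compares the replicates, so this overlap is in part a matter of selection and does not measure reproducibility. No chance value was computed for it. Of its 6064 peaks, 6000 (98.9%) overlapped a peak in both replicate lists and none lacked a partner in both. In each replicate 6032 combined peaks (99.5%, 99.3 to 99.6) had a partner. Most partners were strong: their median rank was 3020 in replicate 1 and 3023 in replicate 2. However, 794 combined peaks (13.1%) had their best partner in replicate 1 at a rank beyond 6064, and 914 (15.1%) in replicate 2. Conversely, 87.6% of the 6040 best nuclear peaks of replicate 1 and 84.6% of the 6042 of replicate 2 overlapped the combined list.

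Binding regions were densest on chromosome III and sparsest on V. The combined list held 87.5 peaks per Mb on III, 1.56-fold the density of the other chromosomes (adjusted p = 0.00033, permutation of 1 Mb bins), and 40.6 per Mb on V, 0.619-fold the others (adjusted p = 0.00033). Chromosome I held 74.5 per Mb, 1.29-fold the others (adjusted p = 0.039, permutation), but with replicate 1 alone the adjusted p was 0.054. Chromosomes II (64.4 per Mb, adjusted p = 0.52), IV (54.8 per Mb, adjusted p = 0.38) and X (52.8 per Mb, adjusted p = 0.26) did not pass the same permutation test. The replicates differed little: with 6064 entries each they gave 88.3 ± 1.41 peaks per Mb on III, 40.6 ± 0.354 on V, 74.1 ± 0.283 on I and 51.8 ± 0.957 on X (SD, n = 2), which measures how repeatable the calls were. Over the bins of the combined list the SD was 25.3 on III and 20.6 on V, and neighbouring bins resemble each other. When the chromosome labels were moved along the genome as blocks, V and I did not pass this permutation test (adjusted p = 0.19 and 0.88). III had an unadjusted permutation p of 0.01, the smallest that 97 placements can give, and an adjusted p of 0.062, the lowest it could reach alone. In 500 kb bins, with 197 placements, III missed the threshold too (permutation p = 0.015, adjusted 0.091). Its adjusted permutation p was 0.12 with replicate 1 alone and 0.062 with replicate 2 alone.

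**Figure D2:**
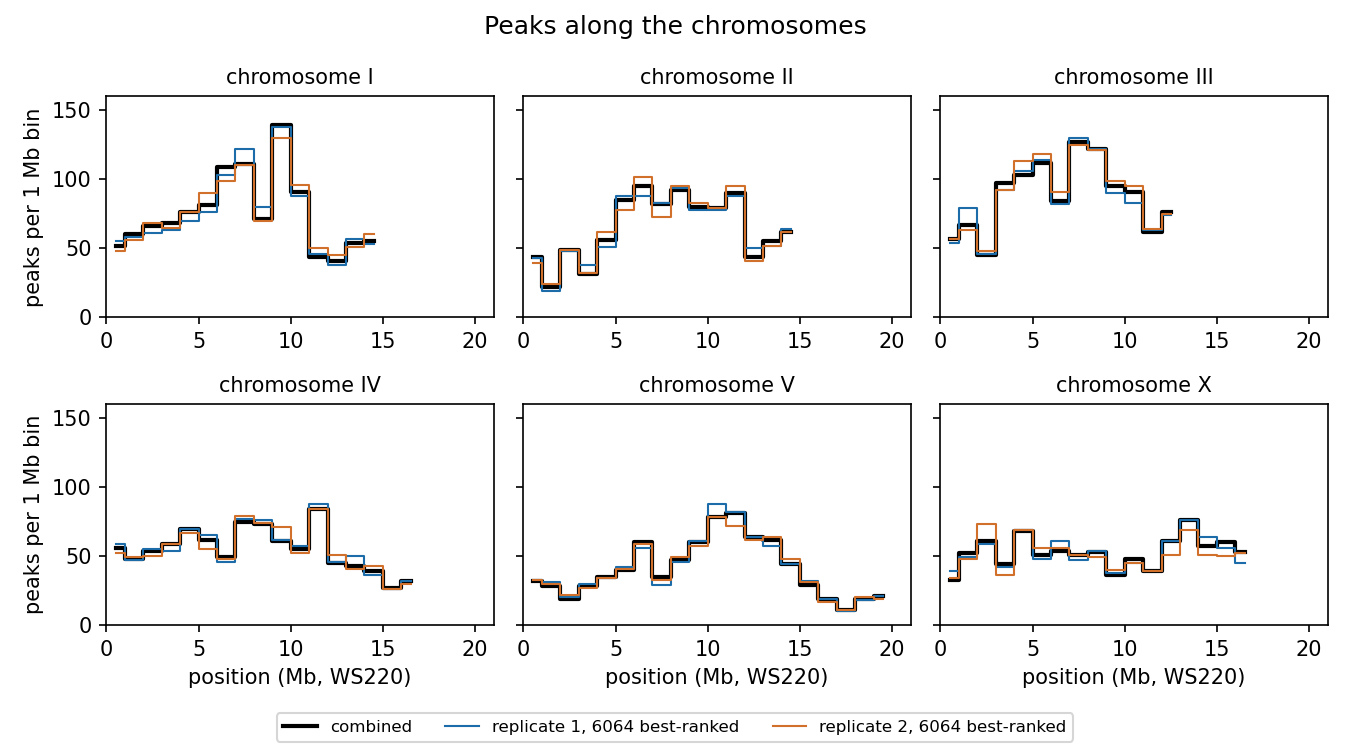
Peaks per 1 Mb bin (vertical axis) are plotted against position in WS220 (horizontal axis, Mb) for each nuclear chromosome, for the combined list (black) and the 6064 best-ranked entries of each replicate (coloured). The fullest bin is at 9 to 10 Mb on I with 139 combined peaks, and the emptiest at 17 to 18 Mb on V with 11.

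On the autosomes, binding regions were concentrated in the middle of the chromosome. With each chromosome divided into 3 equal segments, the central segment held more peaks per Mb than the outer ones on 5 of 5 autosomes, from 1.37-fold on IV to 1.98-fold on V, with a mean of 1.58-fold (p = 0.0008, permutation by shifting peaks around each chromosome). On V the central segment held 61.4 peaks per Mb and the outer ones 30.97. On X the central segment held 47.9 per Mb and the outer ones 55.96, a ratio of 0.856 that did not pass the same permutation test (p = 0.13). The autosomes and X differed from each other in this ratio by 1.85-fold (p = 0.0002, permutation). That test shifts peaks along each chromosome and does not set X, a single chromosome, against the spread of the 5 autosomes (SD of log2 ratios 0.22). Replicate 1 gave a mean autosomal ratio of 1.61-fold and replicate 2 of 1.57-fold. Among entries ranked beyond 20000 the mean autosomal ratio was 0.987 in replicate 1 and 0.999 in replicate 2, with autosomes going both ways: V kept a central excess (1.32-fold and 1.17-fold) and III was lower in the centre (0.822-fold and 0.847-fold). The fall of the mean from the best 6064 entries was itself past the threshold in both (permutation p = 0.0001, the smallest possible, and 0.0012).

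X held few of the strongest regions, as ordered by the number in the peak name. The highest score was shared by 4462 combined entries, 4909 of replicate 1 and 3015 of replicate 2. The choice of the 1516 strongest therefore rests on that number, whose basis is not given. Of the 944 combined peaks on X, 144 (15.3%, 95% interval 13.1 to 17.7) were among the 1516 strongest of the list, against 26.8% of the peaks on the other chromosomes (permutation p = 1e-05, the smallest that 100000 permutations of bins can give, and 6e-05 adjusted over 6 chromosomes). With labels moved along the genome as blocks the permutation p was 0.01 before adjustment, the smallest that 97 placements can give, and 0.062 after it, the lowest it could reach alone. No autosome passed the permutation test of bins in the combined list; the nearest was I at 28.4% (adjusted p = 0.19, permutation), which passed in replicate 1 alone at 29.4% (adjusted p = 0.029, permutation). The replicates gave similar values: 16.18% of the X peaks of replicate 1 and 16.6% of those of replicate 2 were among the 1516 strongest entries, against 26.7% and 26.5% of the peaks elsewhere. Among the 1516 strongest combined peaks X held 8.12 peaks per Mb against 16.7 on the other chromosomes (adjusted p = 0.00021, permutation of bins), a difference that did not pass when labels were moved as blocks (adjusted permutation p = 0.51). X made up 7.80% (5.76 to 10.5) of the best 500 combined peaks, 12.5% (10.6 to 14.7) of ranks 1001 to 2000 and 19% (16.7 to 21.5) of ranks 4001 to 5000, while it spans 17.7% of the nuclear genome.

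**Figure D3:**
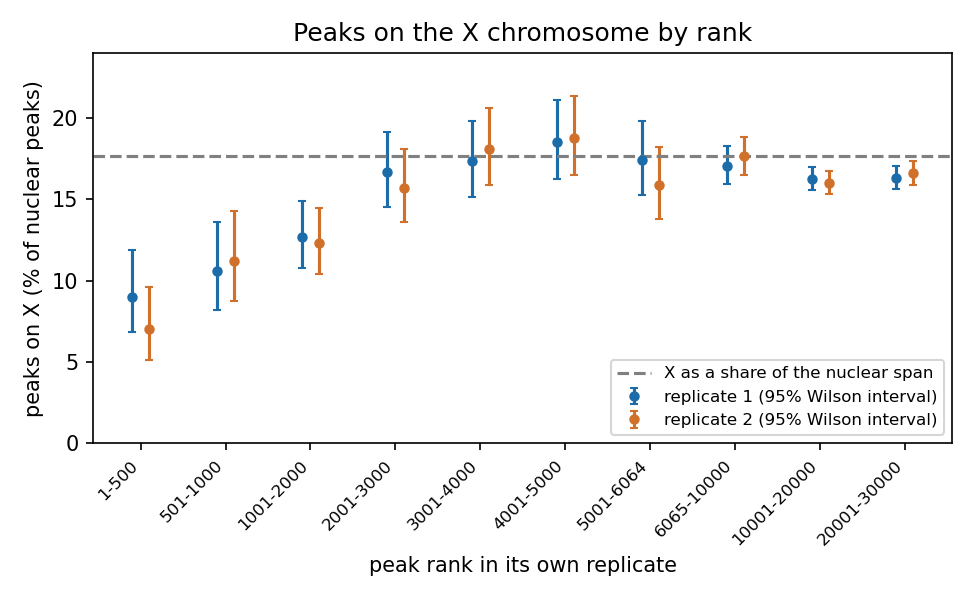
The percentage of nuclear peaks that lie on X (vertical axis) is plotted by rank class (horizontal axis) for both replicates, with 95% Wilson intervals; the dashed line is X as a share of the nuclear span, 17.7%. The share is 9.02% and 7.01% in the best 500 entries of replicates 1 and 2 and 16.3% and 16.6% among ranks 20001 to 30000.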

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

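The tests of explanations in this part were chosen after the results had been seen, except that the bounds for weak peaks inside the gaps on chromosome V were set before that value was computed.

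Both replicate lists held entries on the mitochondrial genome, 26 in replicate 1 and 25 in replicate 2, while the combined list held none; they were singled out because they lie outside the nuclear comparisons. Many repeat an interval already listed: they make up 5 distinct intervals in replicate 1 and 13 in replicate 2. A total of 24 and 22 entries, repeats included, ranked within the best 6064 of their list, and the best ranked 222 and 272. A candidate explanation is the many copies of the mitochondrial genome in the sequenced DNA, which predicts calls over nearly the whole molecule. Peaks covered 96.5% of it in replicate 1 and 87.9% in replicate 2, as predicted. The most covered nuclear stretch of the same length reached 53.1% in replicate 1 and 52.8% in replicate 2. Mitochondrial entries were up to 10609 and 2894 bp wide in replicates 1 and 2, against 789 and 710 bp for nuclear ones. Any signal over the whole molecule would give such coverage. Extra copies would also raise the input, and the lists hold no values of the inputs, so the coverage cannot decide and the explanation stays open. No biological explanation was tested, and the reason for the absence from the combined list is not recorded.

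The low share of X among the strongest peaks was weighed against technical explanations. A loss of calls on X of the same size at every rank is argued against by the log2 ratio of X to the other chromosomes in peaks per Mb. Among ranks beyond 20000 this ratio was -0.12 in replicate 1 and -0.11 in replicate 2, against -0.97 among the 1516 strongest entries of either replicate. In the whole combined list, the yardstick used below for III and V, it was -0.23. A smaller loss of calls on X at every rank therefore stays open. Lower read coverage of X, which could lower the ranks of its peaks without removing them, stays open because the lists hold no coverage. No biological explanation was tested, and weaker binding of LSY-2 on X stays open.

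The high density on III and the low density on V were also present among weak calls. Among ranks beyond 20000 the log2 ratio to the other chromosomes was 0.57 and 0.45 on III and -0.60 and -0.56 on V in replicates 1 and 2, against 0.64 and -0.69 in the combined list. These ratios lay further from zero among strong calls. In the 1516 strongest combined peaks they were 0.77 on III and -0.73 on V. Among ranks 1 to 500 they were 1.027 on III and -1.003 on V. A property of those chromosomes that acts on calls of every rank stays open, such as gene density, chromatin or the ease of placing reads. The deviations were not of the same size at every rank, and their change with rank was not tested. Which property it might be was not tested either. Stretches of V in which no peak can be called were tested through its 38 gaps of over 100 kb between combined peaks. Weak peaks lay in them at 0.337 (replicate 1) and 0.385 (replicate 2) of their density elsewhere on V, between the values set for and against that explanation. The gaps held 207 and 235 weak peaks in replicates 1 and 2, so peaks can be called in parts of them. The gaps were also picked for holding no combined peak, so a lower density of weak peaks there cannot decide the cause. For the remaining parts of the gaps the explanation stays open.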

How the results depend on the processing

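Of 102 alternative values, 86 kept the direction and the side of the threshold and none reversed. The 86 include many for results, such as the densities of II and IV, that missed the threshold in every setting. The comparisons of segments and of each chromosome's share of peaks among the 1516 strongest were chosen after seeing the data. So were the distinct intervals, the 500 kb bins, the moved labels and the use of ranks for scores. The overlap of the replicates passed its permutation test under every overlap rule and peak set tried, with 36.2% to 86.3% overlapping. Score agreement (rho 0.65) was 0.68 with reciprocal 50% overlap, 0.41 for peaks that also overlap the combined list, 0.69 with ranks in place of scores and 0.78 with ranks for those peaks. The share of combined peaks with a partner fell to 87.7% (replicate 1) and 86.4% (replicate 2) with reciprocal 50% overlap, and was 99.8% and 99.97% for the best 3032 combined peaks. Against the other chromosomes, X passed the threshold among the best 3032 (log2 ratio -0.53) and the best 1516 (-1.04) combined peaks, having missed it in the whole list (-0.23). With chromosome labels moved along the genome, I (0.37), III (0.64) and V (-0.69) missed it, as did the share of X peaks among the strongest (15.3%). For III and for that share the unadjusted p in the combined list was the smallest that 97 placements can give. With 500 kb bins, which give 197 placements, III still missed the threshold (permutation p = 0.015, adjusted 0.091). The adjusted permutation p of III was 0.12 with replicate 1 alone, and that of the share of X peaks was 0.12 with replicate 2 alone. X also missed it in density among the best 3032 (adjusted permutation p = 0.70) and the best 1516 (0.51). With a replicate left out, log2 ratios ranged from 0.35 to 0.36 on I, which missed the threshold with replicate 1 alone, from 0.63 to 0.68 on III, -0.70 to -0.68 on V and -0.28 to -0.24 on X; the share of I peaks among the strongest ranged from 28.2% to 29.4%, passing the threshold with replicate 1 alone. The causes of the other changes were not tested. No paired analysis was possible because the lists used here hold the ChIP replicates alone and no values of the inputs. Alternatives on gene windows, gene lists, gene classes and sequence words were not run, for want of an annotation and sequence of the WS220 build, and overlap between replicates cannot be computed with either left out. Read depth is unknown, so a region missing from a list was not detected at an unknown depth and is not shown to be unbound.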

Other observations

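The test of close neighbours was chosen after the lists had been seen. Peak calls lay close together more often than expected by chance. Among 6048 distinct combined intervals, 601 lay within 1 kb of the next one, 1.30-fold the 461 expected when positions were redrawn within 100 kb (permutation p = 0.001, the smallest possible). The replicates gave 1.43-fold and 1.45-fold. With overlapping intervals merged, 513 of 5963 combined regions lay within 1 kb of the next, 1.61-fold the 319 expected without overlap (permutation p = 0.001, the smallest possible), and the replicates gave 1.66-fold and 1.79-fold. Whether calls that lie side by side are parts of a broader region was not tested. The fullest 20 kb window was on II at 10540001 to 10560000, with 17 combined peaks and 15 and 18 in the best 6064 entries of replicates 1 and 2, where the mean window held 1.21. Next came II at 6820001 to 6840000 with 13, III at 1920001 to 1940000 with 13 and I at 7080001 to 7100000 with 11. The II window at 6820001 differed between the best 6064 entries of the replicates, with 8 peaks in replicate 1 and 16 in replicate 2. Replicate 1 was not short of weaker calls there. Over all its entries, its most covered nuclear stretch of the length of the mitochondrial genome ran from 6829093 to 6842995 on II and overlapped this window. These windows were picked for their counts, so no test was made on them.

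Long stretches had no combined peak. Of the gaps of over 100 kb between neighbouring combined peaks, 38 were on V, 23 on X, 19 on IV, 10 on II, 8 on I and 6 on III. The longest ran from 16965956 to 17723171 on V, 757 kb, and held none of the best 6064 entries of either replicate and 7 and 12 of all 30000 entries in replicates 1 and 2. The next, from 2694792 to 3195072 on V, was 500.3 kb long and held 3 and 1 of the best entries.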
